A study of Mus musculus with 80 samples.

How the data were processed

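Total RNA from frozen brain, heart, kidney, liver and lung was hybridised to Affymetrix HT MG-430 PM arrays, 80 in all. Per the submitters' processing notes, RNA isolated with Qiagen RNeasy kits was made into biotin-labelled cRNA, and Affymetrix Expression Console, RMA and Partek were used, with no versions or settings given. The deposited values are log2 expression per probe set, normalised by the authors with RMA before deposit. Whether the arrays of all tissues were normalised together is not stated. The values lay between 2.23 and 14.06 with array medians near 4 in every tissue.

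Of 45141 probe sets, 104 controls were left out. The gene table named 29449 probe sets, of which 28898 had 1 gene and 551 several, and 15588 are unnamed here. A gene was represented by the 1-gene probe set with the highest mean over all arrays, which gave 17097 genes, 7180 of them with several probe sets. Symbols, chromosomes and neighbour order came from the GRCm38.p6 gene table, which matched 28689 of the 1-gene probe sets by gene ID. A gene whose highest group mean lay under the array median was treated as dim.

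Samples were grouped by genotype, sex and tissue from their titles, 4 arrays per group. The heart library of KO female 994 was placed by its title. Tissue labels were checked with marker lists and sex labels with Xist and Y-linked genes, and no library was left out. Animal numbers in the titles were read as 1 animal per number, genotype and sex. Deviations from group means correlated at a median of 0.096 over 132 pairs of arrays from 1 animal, and at -0.0032 over 2428 other pairs. Each tissue was fitted alone, and a fit of all tissues with the animal as a random block (correlation 0.0736) is given beside it where the count moved by more than 1.5 times.

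Tests ran in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. Per tissue, a linear model with group means of genotype by sex was fitted with eBayes. Contrasts were KO minus WT averaged over the sexes, male minus female averaged over the genotypes, and the KO effect in males minus that in females. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as called. Whether the KO effect differed by tissue was tested with a moderated F over all 80 arrays and 20 groups. Genes within 100 measured neighbours on each side of Ces1c were compared with the rest by a two-sided Fisher's exact test.

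Of 64 gene lists written before the data were examined, 54 lists of at least 5 measured genes were tested for KO against WT with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists held 1341 entries, of which 1165 were measured. In an earlier version of the matching 2 entries that are current symbols, Chat and Srebf1, had been read as synonyms of other genes, and after correction no count changed. Male against female was also run through the list tests, which the plan did not hold, and its counts are among the other observations.

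The genes named were chosen by a rule fixed before the data were examined: Ces1c in every tissue, up to 10 called genes in each direction for KO against WT and every called carboxylesterase, up to 5 in each direction for male against female, up to 5 by adjusted p in the interaction and tissue tests, and of each described list some members among the 4 with the smallest p. Other names, such as the extremes of the carboxylesterase list, were chosen after their values were seen.

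Alternatives tried were all probe sets, the mean of a gene's probe sets, bright genes alone, renewed quantile normalisation, median centring, an intensity trend with a robust prior, no moderation, array weights, a minimum of 1.5-fold, a block for the range of the animal number, an animal block over all tissues, each sex or genotype alone, and leaving out each library in turn. Fitting all 80 arrays together without a block and leaving out liver libraries 952 and 994 together were added after the data were seen. Each contrast was compared with 100 regroupings of the arrays. For the sex-by-genotype test, residuals of a model without the interaction were reshuffled over the arrays instead.

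The fits were tested on simulated data. Of differences of 1 log2 unit put into KO against WT, 100% were recovered in brain and kidney, 98.5% in heart, 95.5% in lung and 89.6% in liver. At 0.5 log2 units the shares were 79.1% in brain, 83.6% in kidney, 59.7% in heart, 68.7% in lung and 41.8% in liver. Each simulation changed 67 genes by 0.5, 67 by 1 and 66 by 2 log2 units, with noise drawn independently for each gene. With that many changed genes the adjusted threshold is easier to pass than where few genes change. These shares may therefore overstate what the real comparisons of KO and WT could find.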

Results

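Ces1c encodes the serum carboxylesterase of the mouse, an esterase made by the liver and secreted into plasma, called Es-1 in the sample labels. Rodents have this enzyme in their blood and humans do not, and it binds organophosphate nerve agents, so mice without it were examined as an animal model for nerve agent exposure. Total RNA of untreated mice on a C57BL/6 background was hybridised to HT MG-430 PM arrays. Knockout (KO) and wild-type (WT) animals of both sexes gave brain, heart, kidney, liver and lung, which made 80 arrays in 20 groups of 4, with 16 arrays per tissue. The arrays came from 23 animals, 12 KO and 11 WT. Of these, 16 gave brain, heart, kidney and liver, 9 of which also gave lung, and 7 gave lung only. The number of arrays limits the precision of every comparison. In all 80 arrays the highest of the 5 tissue marker lists was that of the labelled tissue, and Xist and Eif2s3y lay on the side of the labelled sex. The heart library of KO female 994, whose tissue field says lung while its title says heart, was highest for the heart list and was kept as heart.

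The targeted gene was examined first, in every tissue. In the liver, Ces1c was lower in KO than in WT animals by a log2 difference of -2.30 (SE 0.26, 8 arrays per genotype, adjusted p = 0.0032, limma with Benjamini-Hochberg adjustment). The 8 WT livers had a mean of 12.42 ± 0.19 (SD) and lay between 12.11 and 12.63. Of the libraries labelled KO, 7 lay between 9.70 and 10.17 with a mean of 9.84 ± 0.17 (SD), and the library labelled KO male 952 was at 12.04, beside the WT livers. Without that library the difference was -2.59 (adjusted p = 9.08e-11, limma with Benjamini-Hochberg adjustment). With the males alone, where 952 is 1 of the 4 libraries labelled KO, the difference was -1.96 and did not pass. Over all alternatives the adjusted p of limma with Benjamini-Hochberg adjustment lay between 9.08e-11 and 1. The 7 low livers were far above the level of the other tissues, so a signal was measured in KO liver. The array has 1 probe set for this gene, and whether it lies within the altered part of the gene is unknown here.

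**Figure D1:**
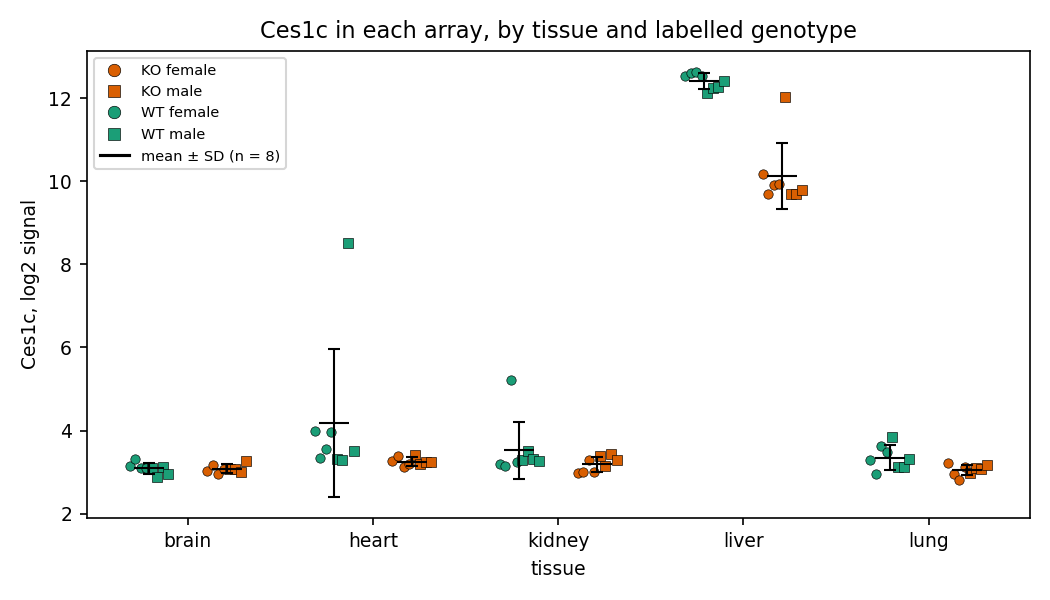
Ces1c expression (log2, vertical axis) in each of the 80 arrays by tissue and genotype, with a point per array and a bar at the group mean. WT livers lie at 12.11 to 12.63, 7 libraries labelled KO at 9.70 to 10.17 and the library labelled KO male 952 at 12.04, while the heart of WT male 903 (8.51) and the kidney of WT female 1264 (5.21) stand above the other arrays of their tissues.

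Outside the liver, Ces1c was near the lower end of the measured range, and no KO difference passed the threshold. The WT means were 3.09 in brain, 3.35 in lung, 3.52 in kidney and 4.18 in heart, where WT male 903 alone was at 8.51. The KO minus WT differences were -0.01 (SE 0.06) in brain, -0.29 (SE 0.12) in lung, -0.33 (SE 0.22) in kidney and -0.93 (SE 0.56) in heart. Leaving out the heart of WT male 903 made the heart difference -0.28, and leaving out the kidney of WT female 1264 made the kidney difference -0.08. WT liver exceeded the mean of the other WT tissues by at least 8.88 log2 units (adjusted p = 1.45e-41, limma over all 80 arrays with Benjamini-Hochberg adjustment). This is a lower bound, because Ces1c was near background in the other tissues and their mean includes the heart of WT male 903.

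The other members of the carboxylesterase family, enzymes that cleave ester bonds of lipids and drugs, were compared to see whether any of them moved with the loss of Ces1c. Of the 13 measured carboxylesterases, Ces1c in the liver was the only one that passed in any tissue. In the liver the other 12 had KO minus WT differences from -0.43 (Ces4a, SE 0.24) to 0.26 (Ces2e, SE 0.25). Adjusted over the list alone, Ces1c in liver and Ces5a in lung passed, the latter a gene below the array median with a difference of -0.25 (SE 0.06). Over all genes Ces5a did not pass (adjusted p = 0.762, limma with Benjamini-Hochberg adjustment).

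Across all 17097 genes, KO and WT animals differed in 1 gene in the heart, 1 in the liver, 1 in the lung, and none in the brain or kidney. In the heart, Lrrc27, a leucine-rich repeat gene, was higher in KO by 1.96 (SE 0.23, adjusted p = 0.00377, limma with Benjamini-Hochberg adjustment), with means of 6.96 ± 0.49 in KO and 5.01 ± 0.55 in WT (SD, 8 arrays each). Each of the 8 KO hearts lay above each of the 8 WT hearts. In the lung, Wdfy1, an adaptor of endosomal toll-like receptor signalling, was higher in KO by 1.91 (SE 0.18, adjusted p = 0.000411, limma with Benjamini-Hochberg adjustment), with means of 8.48 ± 0.26 in KO and 6.57 ± 0.48 in WT. Again each KO lung lay above each WT lung. The third gene was Ces1c in the liver. Without a moderated variance neither Lrrc27 (adjusted p = 0.114) nor Ces1c (adjusted p = 0.0818) passed, both from per-gene variances beside limma with Benjamini-Hochberg adjustment. With females alone Wdfy1 did not pass, and with males alone neither Lrrc27 nor Ces1c did. In 1 model of all 80 arrays without a block, added after the data were seen, Wdfy1 in lung did not pass either (difference 1.91, adjusted p = 0.0893, limma with Benjamini-Hochberg adjustment), and the 2 genes called there in lung were others. Over all alternatives the adjusted p lay between 2.54e-18 and 1 for Lrrc27 and between 3.31e-07 and 0.287 for Wdfy1 (limma with Benjamini-Hochberg adjustment). With all tissues in 1 model and the animal as a block, the counts were 14 genes in brain, 5 in heart, 1 in kidney, 21 in liver and 3 in lung.

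Wdfy1 belonged to a list of genes known to differ between C57BL/6 substrains, and it was higher in KO in the other tissues too, without passing over all genes. Its differences were 1.52 (SE 0.39) in brain, 1.96 (SE 0.48) in heart, 1.68 (SE 0.37) in kidney and 1.47 (SE 0.38) in liver. Adjusted over the list alone it passed in all 5 tissues. The WT spread of Wdfy1 was wide in these tissues, with an SD of 1.45 in the heart against 0.42 in KO. WT animals 876, 902 and 936 had Wdfy1 above the middle of its range in every tissue they gave, and of these 876 alone gave a lung. Lrrc27 was near the lower end outside the heart, and its differences there were -0.25 (SE 0.07) in brain, 0.03 (SE 0.06) in kidney, -0.02 (SE 0.10) in liver and -0.41 (SE 0.08) in lung.

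**Figure D2:**
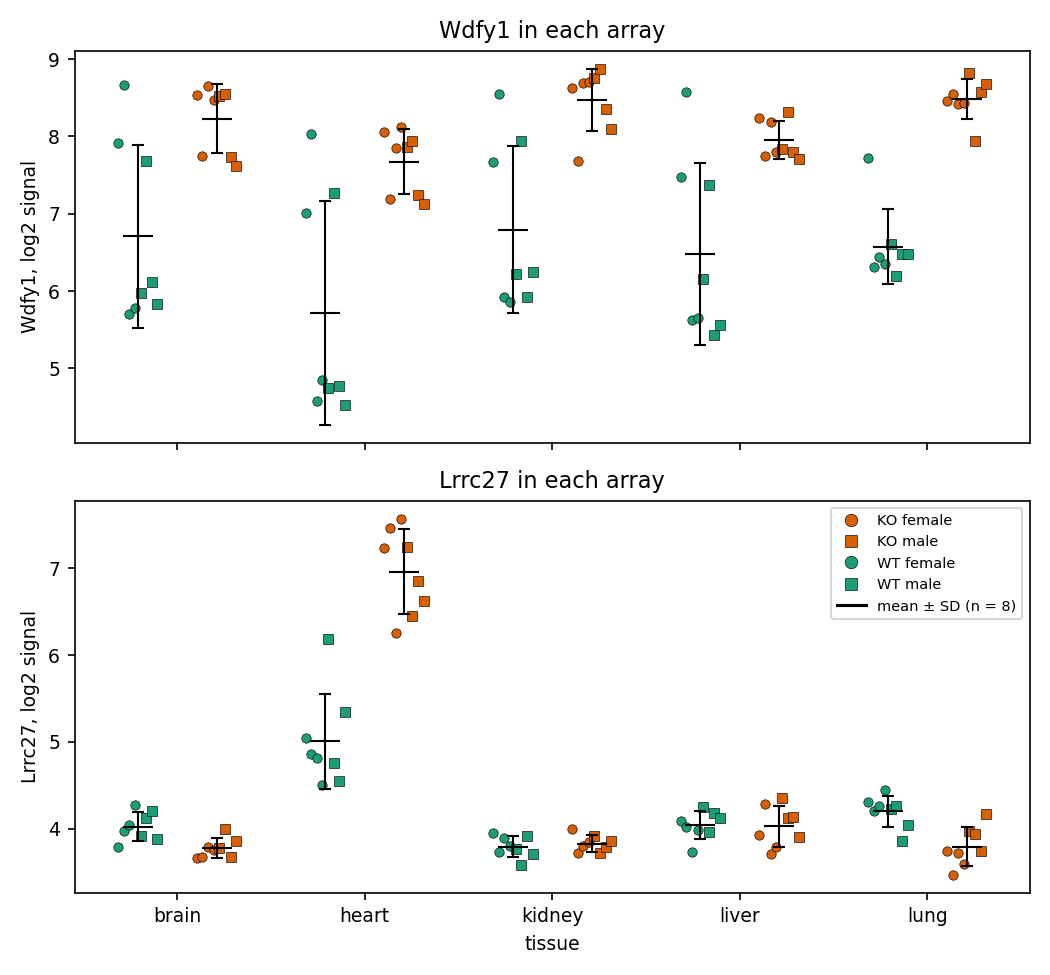
Wdfy1 and Lrrc27 expression (log2, vertical axes) in each array by tissue and genotype, with a point per array and a bar at the group mean. Wdfy1 is high in all KO arrays and in the arrays of WT animals 876, 902 and 936, and Lrrc27 differs between genotypes mainly in the heart, with means of 6.96 in KO and 5.01 in WT.

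The brain was of interest because the enzyme protects against agents that act on cholinesterases. In the brain, limma called 0 genes for KO against WT, with 1021 genes at an unadjusted p under 0.05, and per-gene variances without moderation also called 0. Over all probe sets 1 passed in brain, a probe set of Aen that was not the one representing its gene. It was higher in KO by 0.46 (SE 0.06, adjusted p = 0.0201, limma with Benjamini-Hochberg adjustment). None of the 24 measured genes of cholinergic transmission passed in any tissue, and the list was not called as a whole in brain (camera adjusted p = 0.91, with differences from -0.41 to 0.26). The 34 genes of GABA and glutamate transmission likewise were not called in brain (camera adjusted p = 0.929), nor were the 35 other esterases and serine hydrolases, which include Ache and Bche (camera adjusted p = 0.876). These 3 lists were not called in the other tissues either.

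In the brain, 8 of 54 lists fixed beforehand were called by camera with a preset correlation of 0.01, although no member passed over all genes. None of the 8 passed with an estimated correlation, where their adjusted p lay between 0.293 and 0.799. Neutrophil genes were lower in KO (adjusted p = 2.02e-05, and 0.293 with an estimated correlation), among them the calprotectin subunits S100a9 (-0.77, SE 0.17) and S100a8 (-0.44, SE 0.15) and the protease Mmp9 (-0.22, SE 0.07), 3 genes that passed when adjusted over the list alone. Striatal genes were higher (adjusted p = 0.000359, and 0.728 with an estimated correlation), with the dopamine signalling protein Ppp1r1b at 0.59 (SE 0.20) and the opioid precursor Penk at 0.34 (SE 0.16). The other lists called higher were NRF2 targets, of which Akr1b8 (0.27, SE 0.07) passed over the list alone, oligodendrocyte genes such as Gjb1 (0.29, SE 0.12), and ER stress genes such as Creld2 (0.43, SE 0.14). Called lower were B and plasma cell genes such as H2-Ab1 (-0.28, SE 0.11), interferon response genes such as Gbp2 (-0.20, SE 0.07), and cytochrome P450 genes such as Cyp3a16 (-0.15, SE 0.06). Cyp3a16 lay below the array median in brain, with means of 2.96 in KO and 3.11 in WT. The mean of the liver marker list was 4.94 in the brain of WT female 936 and 4.56 in that of WT male 903. In the other brains it was 3.60 to 4.34. The count of called lists was 5 without the brain of WT female 876 or of WT male 1262.

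In the heart, camera called 3 lists higher in KO, and for each the adjusted p was 0.975 with an estimated correlation. Airway epithelium genes (adjusted p = 0.000626) included the secretoglobin Scgb3a2 at 1.98 (SE 1.12) and Bpifb1 at 1.02 (SE 0.52), and Scgb3a2 had an SD of 3.38 among KO hearts against 0.15 among WT hearts. The mean of the lung marker list stood at 5.76 in the heart of KO female 781 and 6.06 in that of KO male 964, against 3.52 to 3.74 in the other 14 hearts. Extracellular matrix genes (adjusted p = 0.000626, and 0.975 with an estimated correlation) included Col14a1 at 0.36 (SE 0.12) and Col5a1 at 0.26 (SE 0.12). Skeletal muscle genes (adjusted p = 0.02, and 0.975 with an estimated correlation) included Casq1 at 0.54 (SE 0.21) and Tnni2 at 0.91 (SE 0.53). The count was 7 without KO female 982, 5 without WT female 876 or WT male 902, and 8 without KO male 962 or WT male 903. The mean of the liver marker list was 7.86 in the heart of KO female 982, 7.83 in KO male 962 and 10.05 in WT male 903, against 3.64 to 5.26 in the other 13 hearts. Leaving out the heart of KO female 982 gave 3 genes for KO against WT in place of 1.

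In the kidney, limma called 0 genes, with 575 at an unadjusted p under 0.05 and 0 called without moderation, and camera called 12 lists. With an estimated correlation none of the 12 passed, and their adjusted p lay between 0.436 and 0.685. Adipose genes were higher in KO (adjusted p = 9.23e-09, and 0.436 with an estimated correlation), with the lipid droplet protein Cidea at 1.01 (SE 0.30) and Thrsp at 0.92 (SE 0.36), and so were extracellular matrix genes (adjusted p = 6.09e-06, and 0.672 with an estimated correlation), with Col6a3 at 0.45 (SE 0.15). Lipogenesis, circadian clock, heat shock, ER stress and endothelial genes were also called higher. Members of a list did not all move 1 way. In the clock list Cry2 was at 0.45 (SE 0.13) and Arntl at -0.37 (SE 0.13), and in the ER stress list Chac1, the member with the smallest p, was at -0.38 (SE 0.13). Carboxylesterases were called lower (adjusted p = 0.00627, and 0.436 with an estimated correlation), with Ces2b at -0.40 (SE 0.28) and Ces1c at -0.33 (SE 0.22), as were cytochrome P450, B and plasma cell, macrophage and neutrophil genes. In the cytochrome P450 list the member with the smallest p, Cyp2d26, was at 0.23 (SE 0.10). Without WT female 1264 the Ces1c difference in kidney was -0.08, and the mean of the liver marker list in that kidney was 6.84, against at most 6.10 in the other 15. The count was 7 without the kidney of KO male 952.

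In the liver, camera called 8 lists, and for 7 of them the adjusted p was 0.846 with an estimated correlation. Ventricular myocardium genes, which are markers of heart muscle, were lower in KO (adjusted p = 6.08e-05), and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.027) and with fry (adjusted p = 0.037). Its members Myl2 (-0.94, SE 0.27) and Trdn (-0.37, SE 0.10) passed over the list alone. Myl2 had an SD of 0.93 among WT livers against 0.17 among KO livers. Pancreatic acinar genes were also called lower (adjusted p = 9.23e-07, and 0.846 with an estimated correlation), among them the trypsinogen Prss2 at -1.42 (SE 0.71), with SDs of 2.09 in WT and 0.56 in KO. Skeletal muscle, interferon response, macrophage, and B and plasma cell genes were called lower as well, and of the last Cd74 passed over the list alone. Cell cycle genes were called higher (adjusted p = 5.95e-06, and 0.846 with an estimated correlation), with Birc5 at 0.51 (SE 0.26), as were respiratory chain genes. The count was 4 without KO female 985, 5 without the library labelled KO male 952, and 5 without WT male 1262.

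In the lung, camera called 5 lists, and for each the adjusted p was 0.872 with an estimated correlation. Genes of fatty acid oxidation were lower in KO (adjusted p = 0.00057), with the thiolase Acaa2 at -0.33 (SE 0.12), as were T and NK cell genes (adjusted p = 0.00637), with Cd3d at -0.61 (SE 0.27), and macrophage and skeletal muscle genes. Genes of cholesterol synthesis were higher (adjusted p = 0.00374, and 0.872 with an estimated correlation), with Sc5d at 0.38 (SE 0.14). The count was 2 without KO female 1898 or WT female 1265, 3 without KO male 1870 or WT male 1262, 8 without WT female 876, 9 without KO male 1871 and 10 without WT male 903. Leaving out the lung of KO male 1871 gave 2 genes for KO against WT. The mean of the heart marker list was 9.54 in the lung of KO female 781. It was 8.89 in that of WT male 903, against 5.98 to 8.07 in the other lungs.

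Whether the KO effect differed between tissues was tested directly with a moderated F over all 80 arrays, and 5 of 17097 genes passed, with 617 at an unadjusted p under 0.05. Lrrc27 led (adjusted p = 1.26e-15, limma with Benjamini-Hochberg adjustment). Ccl21b, a lymphoid chemokine, was lower in KO brain by -2.32 (SE 0.37) and differed by 0.02 (SE 0.10) in heart and -0.01 (SE 0.08) in kidney (adjusted p = 0.00010). The KO brains of males 962 (7.14) and 964 (7.04) lay within the WT range of Ccl21b, 6.41 to 7.93, and the other 6 KO brains at 3.85 to 4.60. Leaving out either of these 2 brains gave 1 gene for KO against WT in brain in place of 0. The kinase gene Stk32c was lower in KO lung (-0.84, SE 0.16), the somatostatin receptor Sstr3 higher in KO brain (0.52, SE 0.15), and Ano4 lower in KO heart (-0.52, SE 0.13), each with an adjusted p of 0.0437. Stk32c in lung (means 3.57 in KO and 4.41 in WT) and Sstr3 in brain (4.53 and 4.01) were near background, as was Ccl21b in the 6 low KO brains, so the sizes of these differences are uncertain. Ces1c itself did not pass this test (adjusted p = 0.0947). The count was 8 with the animal as a block, and 1 without the brain arrays.

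A targeted locus can carry flanking sequence of the strain in which it was made, so genes around Ces1c were counted apart. Of the 200 measured neighbours of Ces1c on chromosome 8, by gene order in GRCm38.p6, 0 passed for KO against WT in any tissue, against 2 of 16724 genes elsewhere (two-sided Fisher's exact test, p = 1). At an unadjusted p under 0.001 the counts were 0 inside and 65 outside, which is 0.389% of the genes outside. At such low shares 0 calls among 200 genes are likely in any region. The counts therefore show no excess near Ces1c and leave smaller effects of flanking sequence open.

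Whether the KO effect differed between males and females was tested in each tissue, and limma called 0 genes in each of the 5, as did per-gene variances without moderation. At an unadjusted p under 0.05 there were 798 genes in brain, 721 in heart, 655 in kidney, 712 in liver and 1040 in lung. Ces1c in liver fell by 2.65 in females and by 1.96 in males, and the difference between these was 0.69 (SE 0.53). Without the library labelled KO male 952, Ces1c in male liver fell by 2.53 and the difference was 0.11 (SE 0.16). With all tissues in 1 model and the animal as a block, the counts were 3, 2, 1, 69 and 5 genes in the same order. Leaving out KO female 781 or WT female 936 gave 4 and 1 genes in brain, KO male 1259 or WT male 902 gave 1 each in kidney, and KO female 994 gave 1 in liver.

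Between males and females 3701 genes passed in the kidney, 1673 higher in males and 2028 higher in females. With the animal as a block over all tissues 2834 passed in kidney and 2958 in liver, so the order of these tissues depends on the model. The pooled model assumes an equal variance of a gene in all tissues. Fitted alone, the median SE was 0.083 in kidney and 0.121 in liver, so the pooled order is the less safe. The amino acid transporter Slc7a13 was higher in males by 7.41 (SE 0.28, adjusted p = 4.52e-12, limma with Benjamini-Hochberg adjustment), the arachidonic acid epoxygenase Cyp2j13 by 6.87 (SE 0.13), the organic anion transporter Slco1a1 by 6.80 (SE 0.10), Acsm3 by 6.65 (SE 0.20) and Ugt2b37 by 5.99 (SE 0.18). Higher in females were Xist (-6.58, SE 0.11), the amino acid transporter Slc7a12 (-6.30, SE 0.28), the efflux pump Abcc3 (-4.00, SE 0.19), Slc22a27 (-3.45, SE 0.14) and Kynu (-3.38, SE 0.15). Of 22 measured androgen-responsive kidney genes, 16 were higher and 5 lower in males (16 and 6 adjusted over the list alone), including Cyp7b1 (5.94, SE 0.10) and Ugt8a (3.66, SE 0.10). Of the 15 genes of the proximal tubule list, 5 were higher and 3 lower in males (6 and 4 adjusted over the list alone). Where the lower sex was near background, as for Cyp2j13 at 3.28 in females and Xist at 4.55 in males, the difference is a lower bound. In 12 of the called genes another probe set of the gene passed in the opposite direction.

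In 5 other lists the kidney genes that passed were all lower in males. Of all 17097 genes, 2028 passed as lower in males and 1673 as higher, 21.6% in either direction. With an estimated correlation camera called 0 of 54 lists between the sexes in kidney, against 8 at the preset correlation and 17 by fry. Of 32 interferon response genes, 22 were lower in males and none higher, among them the GTPase Gbp3 (-2.56, SE 0.17), Ifit1 (-0.84, SE 0.10) and Usp18 (-0.77, SE 0.11). Of 29 extracellular matrix genes, 12 were lower in males, such as fibronectin Fn1 (-0.86, SE 0.14) and Bgn (-0.52, SE 0.09), and of 15 endothelial genes 10 were lower, such as the angiopoietin receptor Tek (-0.62, SE 0.09) and Esam (-0.44, SE 0.07). Smooth muscle genes were lower in 7 of 11, such as Des (-0.44, SE 0.10), and markers of nephron segments other than the proximal tubule in 10 of 18, such as Ptger3 (-0.82, SE 0.10) and the podocyte protein Podxl (-0.50, SE 0.09). None of these 5 lists had a member that passed as higher in males, which is why they are described here and not a separate result. Adjusted over the list alone the lower counts were 22, 13, 10, 7 and 17. Among carboxylesterases 5 were higher in males, led by Ces1g (4.28, SE 0.29) and Ces1f (2.37, SE 0.08), and Ces2g was lower (-0.64, SE 0.13).

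In the liver 848 genes passed, 339 higher and 509 lower in males. The fatty acid hydroxylase Cyp4a12a was higher in males by 7.88 (SE 0.15, adjusted p = 4.26e-15, limma with Benjamini-Hochberg adjustment), the steroid enzyme Hsd3b5 by 7.61 (SE 0.37), the fatty acid elongase Elovl3 by 5.62 (SE 0.26), the Y-linked Eif2s3y by at least 5.22 and Serpina4-ps1 by 4.97 (SE 0.51). Higher in females were the sulfotransferases Sult2a2 (-7.60, SE 0.17) and Sult3a1 (-6.93, SE 0.24) and the cytochromes Cyp3a41a (-6.67, SE 0.25), Cyp2b13 (-6.59, SE 0.25) and Cyp2b9 (-6.40, SE 0.35). Where the lower sex was near background, as for Cyp4a12a at 3.56 in females and Sult2a2 at 3.25 in males, the difference is a lower bound. Of 21 genes listed as male-biased in liver, 16 were higher and none lower in males, and of 24 listed as female-biased, 21 were lower and none higher (adjusted over the list alone, 18 of the former were higher, and of the latter 22 lower and 1 higher). Interferon response genes were lower in males in 8 of 32, with Gbp3 at -1.46 (SE 0.21), and macrophage genes in 6 of 22, with the Fc receptor Fcgr1 at -1.22 (SE 0.24) and the complement subunit C1qa at -0.70 (SE 0.15). Of the carboxylesterases 5 were higher in males, led by Ces2b (2.27, SE 0.31). With an estimated correlation camera called 0 of 54 lists between the sexes in liver, against 10 at the preset correlation and 6 by fry. With the animal as a block over all tissues, 2958 genes passed, and without the libraries 952 and 994, left out after the data were seen, 1103 passed. Without the liver of KO female 994 alone 1271 passed, and without that of WT male 902 alone 578. The liver of KO female 994 had a Gapdh 3' control signal of 11.42, against 12.23 to 12.66 in the other livers. Its mean correlation with the liver arrays was 0.953, the lowest of the livers.

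**Figure D3:**
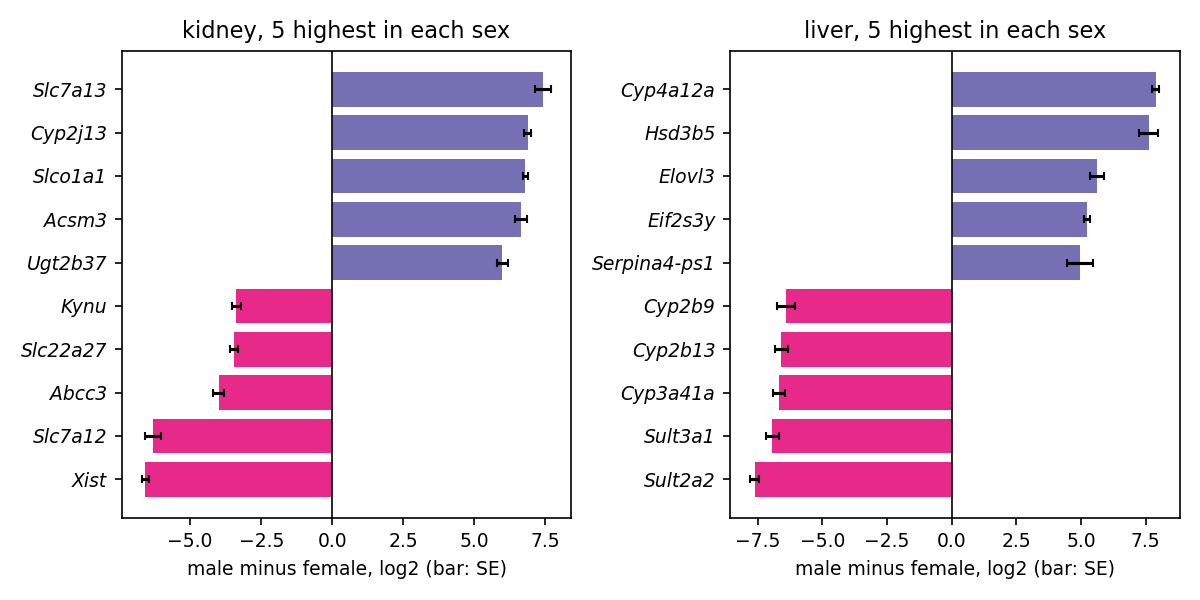
Male minus female differences (log2, horizontal axes, error bars of SE) in kidney and liver, for the 5 called genes with the largest difference in each direction. Genes were called by limma with Benjamini-Hochberg adjustment. In kidney the genes run from Slc7a13, higher in males, to Xist, higher in females. In liver they run from Cyp4a12a, higher in males, to Sult2a2, higher in females.

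In the heart 46 genes passed, 5 higher and 41 lower in males, 13 of them on the X or Y chromosome. Apart from those, the glucocorticoid-activating enzyme Hsd11b1 was higher in males by 1.01 (SE 0.14, adjusted p = 0.00387, limma with Benjamini-Hochberg adjustment) and the actin-capping protein Tmod4 by 0.55 (SE 0.11, adjusted p = 0.0439). The call of Tmod4 was lost in 17 of 30 alternatives, with values from 0.34 to 0.76. The matrix genes Col14a1 (-0.98, SE 0.12) and Lum (-0.83, SE 0.14), with Tmem45a (-0.92, SE 0.16) and Adamtsl3 (-0.79, SE 0.11), were lower. With the arrays quantile normalised again 29 genes passed, 8 higher and 21 lower, and with the animal as a block over all tissues 130 passed, which included 33 of the 46. The count was 28 without WT male 901 and 29 without WT female 1265.

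In the brain 17 genes passed, 8 higher and 9 lower in males, 6 of them on the X or Y chromosome. Outside these chromosomes Chd4 (0.70, SE 0.12) and Pnn (0.69, SE 0.12) were higher, and Ap2a1 (-0.55, SE 0.09) and Rhoc (-0.53, SE 0.09) lower, with adjusted p from 0.0287 to 0.0332 (limma with Benjamini-Hochberg adjustment). These calls were lost in 15 of 30 alternatives for Chd4 (0.32 to 1.08), 17 of 30 for Pnn (0.22 to 1.15), 13 of 30 for Ap2a1 (-0.61 to -0.50) and 15 of 29 for Rhoc (-0.79 to -0.26). With the animal as a block over all tissues 30 genes passed, which included 8 of the 17. The even split by direction did not hold over all probe sets, where 96 were higher and 30 lower in males. With WT only, 23 genes were higher and 4 lower. The count was 32 without KO female 994, 11 without WT male 903, 10 without WT female 876, 9 without WT male 901, 8 without KO male 962, WT male 902 or WT male 1262, 7 without KO male 964, and 6 without KO female 985 or KO male 952.

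In the lung 9 genes passed, all on the X or Y chromosome, with 3 higher and 6 lower in males. They included Kdm6a (-0.76, SE 0.08), 5530601H04Rik (-0.75, SE 0.12) and Kdm5c (-0.64, SE 0.09), X-linked genes lower in males. The call of 5530601H04Rik was lost in 16 of 30 alternatives, with values from -0.96 to -0.49. The count was 24 with the animal as a block over all tissues. In all 5 tissues the same 5 genes passed: Xist and Eif2s3x, lower in males, and Eif2s3y, Kdm5d and Uty, higher in males. Of the 5 measured Y-linked genes, 3 were higher in males in each tissue. In brain, heart and lung, Xist fell by at least 6.52, 5.15 and 6.57 in males, and Eif2s3y was higher by at least 3.50, 5.22 and 4.82. Xist is silent in males and females lack the Y-linked Eif2s3y, so the lower values are background and these are lower bounds.

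Kidney and liver shared 337 genes called between the sexes, 87 higher in males in both, 184 lower in both and 66 in opposite directions. Independent lists of these sizes would share 33.2 genes higher in both and 60.4 lower in both, although the kidney and liver arrays came from the same 16 animals.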

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

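The tests of a label swap, of an intact Ces1c gene, of Wdfy1 and of Ces1c made by the heart itself were chosen after the results were seen.

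Single libraries stood apart from the other 3 of their group in 12 of 80 uses of Dixon's test, on 4 measures in each of 20 groups, where chance gives about 4. For Ces1c these were the liver library labelled KO male 952 at 12.04 (others 9.70 to 9.78), the heart of WT male 903 at 8.51 (others 3.30 to 3.50), the kidney of WT female 1264 at 5.21 (others 3.16 to 3.25) and the kidney of KO female 985 at 3.28 (others 2.99 to 3.00). For Wdfy1 they were the kidney of KO female 982 at 7.69 (others 8.63 to 8.70), the lung of WT female 876 at 7.73 (others 6.31 to 6.44), and WT male 902 in brain at 7.68 (others 5.83 to 6.12), heart at 7.26 (others 4.52 to 4.77) and kidney at 7.94 (others 5.93 to 6.24). By mean correlation with the arrays of their tissue they were the liver of KO female 994 at 0.953 (others 0.980 to 0.982) and the heart of KO female 781 at 0.987 (others 0.98907 to 0.98913). The lung of WT female 1264 at 0.991 (others 0.9880 to 0.9884) stood apart by a higher correlation than its group.

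The KO effect differed between tissues in 5 genes by the moderated F of limma with Benjamini-Hochberg adjustment. Adjusted p was 1.26e-15 for Lrrc27, 0.00010 for Ccl21b, and 0.0437 each for Stk32c, Sstr3 and Ano4. In the 100 regroupings of animals, 24 gave as many genes and the highest other gave 331, so chance is not excluded for the count.

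Probe sets unnamed here and left out of the gene comparisons also differed between KO and WT. In liver 1 of them was higher in KO by 1.62 (SE 0.19) and another lower at -1.51 (SE 0.20), and in lung 1 was lower at -1.45 (SE 0.19).

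The liver library labelled KO male 952 had Ces1c at the level of the WT livers. A swap with a WT liver of the series would leave a WT library among the low ones, and 0 WT livers lay at or below the highest other library labelled KO. RNA of another animal is argued against, since over 100 genes that vary between animals its own brain, heart and kidney ranked 1 of 16, as for 13 of 15 other livers. An animal with an intact Ces1c gene cannot be told apart from the rest, because outside the liver the median of Ces1c in WT lay only 0.152 log2 units above its median in the other KO animals. A mixture with WT liver RNA was not tested and stays open.

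Wdfy1 was higher in KO lung, the tissue where it passed. Loss of Ces1c as the sole cause is argued against by 1 WT animal, number 936, that reached the lowest KO level in all of its tissues. A sequence variant under 1 probe set is argued against too, as 4 probe sets of the gene were higher past the threshold. A background locus that differs between WT animals may explain the difference: 0 WT animals with 4 or more tissues were high in some and low in others, while 3 of 11 were high throughout and 8 low. High means above the middle of the range in a tissue. Of the low animals, 1951, 1953 and 1960 gave only a lung and could not have been mixed. Of the high ones, 876 reached the lowest KO level in 1 of 5 tissues and 902 in 3 of 4. The background locus is a hypothesis found and tested on the same arrays, and no genotype of the animals was analysed here.

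Ces1c stood at 8.51 in the heart of WT male 903. Ces1c made by the heart alone is argued against, because 9 of 9 measured liver check genes were highest in this library among the 16 hearts. Liver transcripts as a set were raised in this library. Of 224 liver transcripts 211 were above every other heart, with a median implied share of liver RNA of 1.86%. Ces1c implied 7.26%, at percentile 90.2 of these shares and just outside the range of 0.585% to 6.63% between the 10th and 90th percentiles set beforehand. Some liver transcripts lie outside that range by its definition, so this place does not argue against liver RNA. Whether liver RNA accounts for all of the Ces1c signal stays undecided.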

How the results depend on the processing

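Leaving out liver libraries 952 and 994 together and fitting all 80 arrays in 1 model without a block were chosen after the data were seen.

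Of the values of named genes under the alternatives, 1520 kept their direction and side of the threshold, 121 kept the direction and no longer passed, and 8 reversed. The minimum of 1.5-fold was not applied to single genes, here or in the counts of lost calls above, so under it each stayed unchanged by construction. The 1520 also include Ces1c where it was never called, in 21 fits in brain and 29 each in heart, kidney and lung. The tally therefore overstates how stable the calls were. The reversals were all of Ces1c in brain, at 0.0916 with males only and 0.0120 with renewed quantile normalisation, and in 6 fits that left out 1 library, where the value reached 0.0184. Over all fits that left out 1 library Ces1c in brain lay between -0.0338 and 0.0184. Counts stayed within 1.5 times the reported value in 154 cases and moved further in 76, leaving out single libraries aside. Unless said otherwise the cause was not tested.

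Pooling all tissues in 1 model moved most counts. With the animal as a block, KO against WT gave 14 genes in brain, 5 in heart, 1 in kidney, 21 in liver and 3 in lung, and without the block 13, 5, 1, 22 and 2. The sex-by-genotype test gave 3, 2, 1, 69 and 5 with the block and 4, 2, 1, 70 and 7 without. Male against female gave 30 in brain, 130 in heart, 2958 in liver and 24 in lung with the block, and 34, 130, 2919 and 23 without. Without the block the 2 genes called in lung did not include Wdfy1. The nearly equal counts with and without the block show that the pooling moved them. Pooling assumes an equal variance of a gene in all tissues. Fitted alone, the median SE for KO against WT was 0.121 in liver, against 0.079 in brain, 0.092 in heart, 0.083 in kidney and 0.090 in lung. The pooled liver counts may therefore be too high, which was not tested.

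KO against WT gave 1 gene in brain and 0 in lung with females only, and 0 in heart, 0 in liver and 2 in lung with males only. In liver Ces1c passed with females only and not with males only, where the library 952 at 12.04 is 1 of the 4 labelled KO. Male against female gave 4 in brain, 4 in heart, 1338 in kidney and 106 in liver with KO only, and 27, 9, 1661, 504 and 3 in brain, heart, kidney, liver and lung with WT only.

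All probe sets gave 1 in brain, 3 in liver and 5 in lung for KO against WT, 126 in brain, 5876 in kidney and 23 in lung for male against female, and 1 for the sex-by-genotype test in lung. Without moderation KO against WT gave 0 in heart and 0 in liver, and male against female 6 in brain and 18 in heart. A minimum of 1.5-fold left 8 in brain, 25 in heart, 888 in kidney and 521 in liver between the sexes. Between the sexes in heart, the animal-number block gave 74 and quantile normalisation 29, and array weights gave 1709 in liver.

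The count of genes whose KO effect differs by tissue was 1 without brain, 3 without heart, 3 without kidney, 2 without liver, 2 without lung arrays, and 8 with the animal as a block. Camera with an estimated correlation and fry each called 0 lists in brain, heart, kidney and lung and 1 in liver. Without liver libraries 952 and 994, KO against WT gave 1 gene and 9 lists and male against female 1103 genes.

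With each library left out in turn, KO against WT ranged from 0 to 1 gene in brain, 1 to 3 in heart, 0 to 0 in kidney, 1 to 1 in liver and 1 to 2 in lung. Lists ranged from 5 to 12, 2 to 8, 7 to 17, 4 to 11 and 2 to 10. Male against female ranged from 6 to 32, 28 to 67, 3087 to 3850, 578 to 1271 and 7 to 10. The sex-by-genotype test ranged from 0 to 4, 0 to 0, 0 to 1, 0 to 1 and 0 to 0. No second Ces1c probe set exists on the array, so that alternative gave no value. Signal near background limits Ces1c outside the liver.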

Other observations

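The test of gene clusters and the KO difference averaged over tissues were chosen after the results were seen, as were the list tests for male against female.

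Each comparison was set against 100 regroupings of its arrays, the real one included, with residuals reshuffled in place of regrouping for the sex-by-genotype test. For KO against WT, 100 gave as many genes in brain (real 0, highest other 2), 5 in heart (real 1, highest other 1), 100 in kidney (real 0, highest other 34), 5 in liver (real 1, highest other 2) and 4 in lung (real 1, highest other 10). Fewer than 5 of 100 was the limit set beforehand, which the lung count met and those in heart and liver did not. As other regroupings in lung gave as many genes and up to 10, chance is not excluded for the lung count either. In brain and kidney the real count was 0, which every regrouping reaches, so nothing is decided there. The kidney regrouping with 34 genes put all 4 animals of the middle range of animal numbers on 1 side, and the lung regrouping with 10 put all 7 of the highest range on 1 side, which points to a structure of the samples. With the range of the animal number as a block, KO against WT gave 0 genes in brain, 1 in heart, 0 in kidney, 1 in liver and 1 in lung.

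For the lists called between KO and WT, as many were called in 29 regroupings in brain (real 8, highest other 14), 97 in heart (3 and 25), 21 in kidney (12 and 16), 48 in liver (8 and 17) and 87 in lung (5 and 20), so chance is excluded for none of these counts. For male against female it was 1 in brain (17 and 4), 1 in heart (46 and 23) and 1 in kidney (3701 and 1378). It was 1 in liver (848 and 5) and 2 in lung (9 and 322). In brain, heart, kidney and liver no other regrouping reached the real count, which argues against chance there. In lung another regrouping gave more genes, so the count alone does not exclude chance. The lung regrouping with 322 genes points to a structure other than sex. For the sex-by-genotype test the highest other count was 2 in brain, heart, liver and lung and 106 in kidney. All 100 gave as many as the real 0 in each tissue, which any count does, so this decides nothing.

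Genes with a KO difference in any tissue at an unadjusted p under 0.001 included neighbours on chromosome 7, Stk32c, Lrrc27, Zfp511 and Mtg1, and on chromosome 4, Ccl21b, Ccl19 and Fam205a1. A chromosome segment that differs between KO and WT animals may lie behind such clusters. The densest window of 50 genes held 4 of the 67 genes, against a median of 3 in 10000 permutations of gene order (permutation test, one-sided p = 0.0559), which leaves this open. Averaged over tissues with the animal as a block, 3 genes passed, Wdfy1 at 1.69, Mtg1 at -0.27 and Fam205a1 at -0.29. The block used 1 correlation of 0.0736 for all genes, although Wdfy1 was high or low in all tissues of an animal. For Wdfy1 several arrays of 1 animal thus counted almost as separate animals, which makes its call here too sure.

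Camera at the preset correlation called 4 lists in brain, 12 in heart, 8 in kidney, 10 in liver and 8 in lung for male against female, and 0 in each tissue with an estimated correlation. Fry called 17 in kidney, 6 in liver and 0 in brain, heart and lung.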
